A study of Homo sapiens with 20 samples.

How the data were processed

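RNA-seq was measured in 20 libraries of H1 human embryonic stem cells, in 10 groups of 2 replicates: unmodified hESC, unmodified cells at SE day 3, shFOXO4 and shSP6 cells at day 3 and day 7, and the 4 scramble groups that belong to them. Per the labels' protocols, total RNA was extracted with a MolPure kit and libraries were made with the TruSeq Stranded mRNA kit. The submitters' processing notes name Trimmomatic 0.39, STAR 2.6.1, RSEM 1.3.0 and DESeq2 1.20.0 with genome build hg19, and give neither the role nor the order of these tools. The deposited values are normalized counts (a signal scale), which the authors made with DESeq2, per the names of the tables, in 5 tables of 4 libraries, each scaled on its own 4 libraries. The tables of the knockdowns name columns by arm and replicate only, so the day and the scramble group of a column were taken from the name of its table. The filter that decided which genes a table lists was not stated. Tables listed 24118 to 29961 genes each, and 22687 gene identifiers were in all 5.

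The step of 1 read was sought in each library from its low values. In 18 of the 20 libraries 100% of the values became whole numbers, within a tolerance of 0.001 read, after multiplication by 1 size factor per library. Recovered reads per library ran from 14937104 to 30328846. In the other 2 libraries (scramble replicate 2 of shFOXO4 day 7 and scramble replicate 2 of shSP6 day 3) the step lay too near 1 for the criterion, and no reads were taken from them. The SD between replicates of log2 values across tested genes was 0.183 to 0.303 per group, and the Pearson correlation between replicates 0.989 to 0.995. Replicates were checked not to be copies of each other: the chi-square per degree of freedom between them was 3.11 to 22.6. For a group with 0 reads in both libraries the floor was 3 counts over the group, and a fold against it is written as "at least". Such floors cover counting error only.

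The main test was limma 3.58.1 in R 4.3.3 (lmFit and eBayes with trend, two-sided moderated test) on log2(value + 1) of the deposited values, within each table, for genes with a mean of at least 10 over its 4 libraries. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. Fold changes are on the log2(value + 1) scale, which understates the change of genes with low values. The difference between 2 knockdown effects was tested with limma over the 8 libraries of both tables, with 1 mean per group and the contrast of the 2 within-table differences, for genes with a mean of at least 10 in both tables. Correlations of knockdown effects were computed across genes.

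A total of 24 gene lists with 451 genes were tested with limma's camera (preset correlation 0.01, two-sided), with adjustment over the lists of at least 5 tested members. They were pluripotency, surface ectoderm regulators, simple epithelium, keratinocyte, amnion, trophoblast, neural ectoderm, neural crest, placode, mesoderm and primitive streak, endoderm, mesenchymal, BMP targets, WNT targets, retinoic acid targets, FOXO targets, FOXO family, SP family, chromatin modifiers, proliferation, p53 targets, interferon response, ATF4 stress and mitochondrially encoded genes. Some genes belong to more than 1 list. A total of 14 list genes were in no table and were not analysed here. The 500 genes most raised and the 500 most lowered at an adjusted p under 0.05 in unmodified day 3 cells formed 2 further sets, tested with camera in each knockdown. No camera call of a gene list held with a correlation estimated from the libraries. Medians were also taken with genes at 0 reads in a group set at their bound, and are given where they differ.

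Named genes followed a rule: FOXO4 and SP6, and POU5F1, NANOG, SOX2, TFAP2A, TFAP2C, GATA3, GRHL2, TP63, KRT8, KRT18, KRT5 and KRT14, in every comparison; the 5 highest and 5 lowest changes among called genes with a mean of at least 100 and both libraries of one group above both of the other; up to 4 called members of each list; and the 3 highest and 3 lowest differences between effects. Clone and locus placeholders (RP11-, AC0, LOC, CTD-, LINC, open reading frame and D-segment names and the like) were left out. The text names a part of the genes that this rule gives. The lists, the tests described above, the rule for named genes, the sets and all but 1 of the alternatives were fixed before the data were examined. Tests of a mixture of cells, of the SP6 hairpin acting on FOXO4 RNA, of the interferon response and of gene families were chosen afterwards. Gene symbols came from the GENCODE v29 and RefSeq names of the reference, which gave 24792 of 31155 identifiers a symbol. That reference is on another genome build than the deposited values, so no positions are given.

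Alternatives were a pseudocount of 0.5 or 5, no filter beyond a mean above 0, a mean of at least 50 (100 for the correlations), TMM factors, quantile normalization, an absolute log2 fold change of at least 1, 1 limma fit over all 20 libraries, the replicate number as a block, leaving out each library in turn, a camera correlation estimated from the libraries, fry, and sets of 200 genes or of all genes past a 2-fold change. For the 2 sets, the alternative with no filter was added after seeing the data. With a library left out, its group's other library was assumed to vary like the other groups. edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 were run on recovered reads in the 3 tables where all 4 libraries gave reads. They were not run for shFOXO4 day 7 and shSP6 day 3, nor was edgeR for the differences between effects.

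The scripts were tested on simulated data with means taken from each table and 50 changed genes per fold and table. All genes of a table shared 1 spread, its median over genes with a mean of at least 100. Spread that differs between genes, and scaling when most genes change, were not simulated. The main test recovered 49 to 50 of 50 genes changed 4-fold, 42 to 48 changed 2-fold, 39 to 44 changed 1.5-fold and 13 to 32 changed 1.25-fold, with 1 to 12 false calls among 15707 to 17577 genes tested. Groups of 2 are too small for a test of single outlying samples or for counting other splits of the samples, and neither was done.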

Results

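RNA was sequenced from 20 libraries of H1 cells, an established line of human embryonic stem cells (hESC), in 10 groups of 2 samples. Unmodified hESC were set against unmodified cells at day 3 of differentiation to surface epithelium (SE), the stage that the labels call initiating. In 4 further comparisons, cells with a short hairpin RNA (shRNA) against FOXO4 or SP6 were set against cells with a scramble shRNA, a control hairpin, at day 3 or at day 7 of differentiation, and each comparison had its own scramble samples. FOXO4 is a transcription factor of the forkhead family and SP6 one of the SP zinc finger family. The question was which genes change on the way to surface epithelium and which of these changes depend on FOXO4 and SP6. Between 14937104 and 30328846 reads per library could be recovered for 18 libraries. The other 2 had normalized totals of 18887684 (scramble replicate 2 of shFOXO4 day 7) and 20305180 (scramble replicate 2 of shSP6 day 3). Levels are normalized read counts given as mean ± SD (SD, n = 2), and changes are log2 fold changes ± SE. Each comparison was scaled separately, so levels of different comparisons stand side by side here without a test. The labels do not say that the samples of a group were separate cultures, so every p-value measures only the spread between these samples, which may be technical.

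FOXO4 and SP6 both rose on the way from hESC to day 3, and each was lower in cells with the hairpin against it. Genes that differentiation raises were mostly lower in both knockdowns, so the share left does not measure the hairpin alone. FOXO4 RNA was also low in shSP6 cells at day 7 but not at day 3, whereas SP6 RNA was low in shFOXO4 cells on both days. FOXO4 (ENSG00000184481) measured 394 ± 22.5 in hESC and 2254 ± 113 in SE day 3 cells, a change of 2.51 ± 0.07 (adjusted p = 2.77e-12). SP6 (ENSG00000189120) measured 86.9 ± 8.01 in hESC and 2346 ± 49.2 in SE day 3 cells, a change of 4.74 ± 0.09 (adjusted p = 9.85e-14). In shFOXO4 cells, FOXO4 fell from 1951 ± 107 to 320.3 ± 2.30 at day 3, which left 16.4% of the scramble level (change -2.60 ± 0.06, adjusted p = 1.18e-32). At day 7 it fell from 1107 ± 139 to 35.5 ± 0.044, which left 3.21% (change -4.92 ± 0.15, adjusted p = 1.03e-08). SP6 in the same cells fell from 1219 ± 109 to 417 ± 30.1 at day 3 (change -1.55 ± 0.07, adjusted p = 6.69e-23). By day 7 its level was 489 ± 44.9 against 5049 ± 257 in scramble cells (change -3.37 ± 0.08, adjusted p = 3.08e-09). In shSP6 cells, SP6 fell from 1865 ± 105 to 262 ± 84.1 at day 3, which left 14.1% (change -2.86 ± 0.16, adjusted p = 2.35e-07). Day 7 levels of SP6 were 3558 ± 733 in scramble and 89.4 ± 5.19 in shSP6 cells, which left 2.51% (change -5.28 ± 0.14, adjusted p = 4.71e-09). FOXO4 in shSP6 cells measured 3274 ± 109 against 3431 ± 492 in scramble cells at day 3, a change of -0.06 ± 0.09 (adjusted p = 0.571). Without scramble replicate 1 that change was -0.21, with an adjusted p of 4.25e-04, and without scramble replicate 2 it was 0.086, with an adjusted p of 0.158. FOXO4 at day 7 fell from 1358 ± 218 to 239 ± 19.9 in shSP6 cells (change -2.49 ± 0.13, adjusted p = 2.46e-07).

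**Figure D1:**
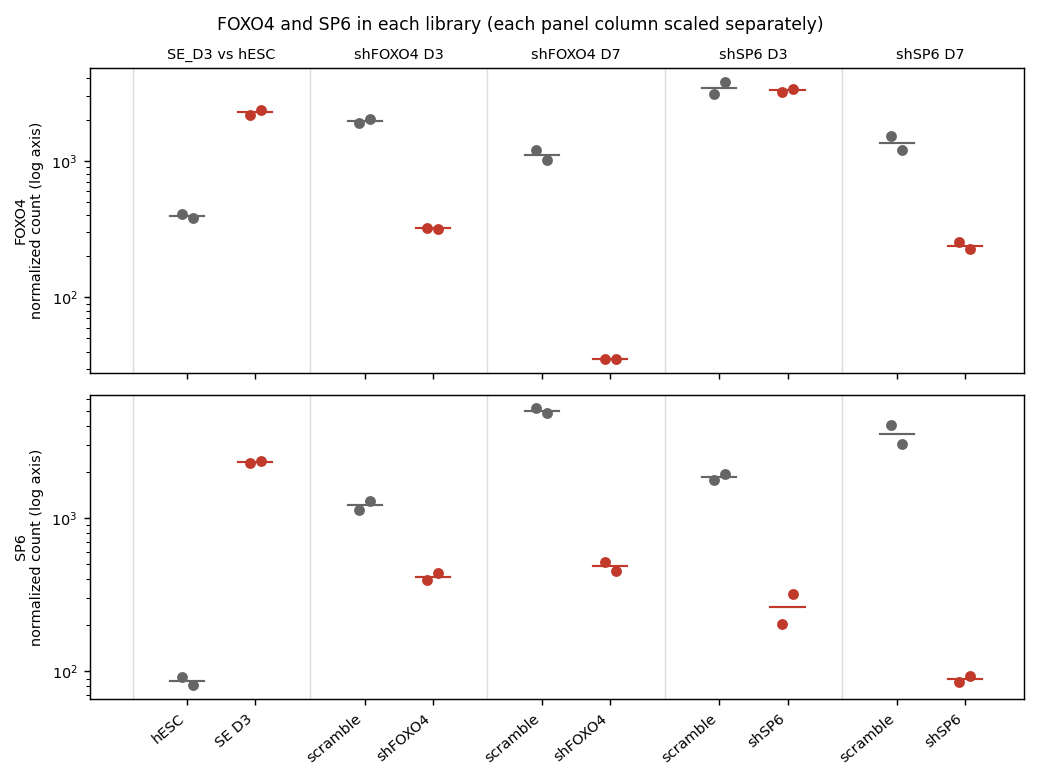
Normalized counts (log axis) of FOXO4 (top) and SP6 (bottom) in each of the 20 libraries, as points, with the group mean as a line, hESC and scramble samples in grey and SE or knockdown samples in red. Both shSP6 day 3 samples lie within the range of the scramble samples for FOXO4 (3197 and 3351 against 3084 and 3779), while every other knockdown pair lies below its scramble pair for both genes.

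Unmodified cells at day 3 had switched on regulators of surface ectoderm and raised simple-epithelium keratins while lowering part of the pluripotency network. All BMP targets tested rose with them, as did most retinoic acid targets and most genes of the amnion list. The keratins KRT5 and KRT14 were not yet expressed. Of 16217 genes tested, 11710 changed, 5712 higher and 5998 lower in SE day 3 cells, and 1981 rose and 2661 fell by at least 2-fold. The median change was -0.020, because the scaling sets the typical gene near no change. The split into higher and lower genes, here and in the knockdowns, follows this in part. Several regulators with no reads in hESC were abundant at day 3. HOTAIRM1 reached 3920 ± 127 (at least 2613-fold higher), DLX5 2515 ± 20.1 (at least 1676-fold) and CDX2 1753 ± 49.6 (at least 1169-fold). TBX3 measured 0.541 ± 0.766 in hESC and 5198 ± 162 at day 3. The 5 largest falls among genes with a mean of at least 100 were in metallothioneins. MT1G fell from 3062 ± 301 to 0 (at least 2041-fold lower), MT1H from 1147 ± 102 to 0 (at least 764.9-fold) and MT1X from 240.8 ± 9.80 to 0 (at least 160.5-fold). MT1E measured 981 ± 129 and 1.42 ± 2.004, and MT2A fell from 1532 ± 53.1 to 10.6 ± 2.92 (change -7.07 ± 0.17).

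Among the surface ectoderm regulators, 21 of 22 rose and 1 fell, with a median change of 6.06 (5.76 with genes at 0 set at their bound), and the list moved against the other genes (adjusted p = 5.20e-11, and adjusted p = 0.217 with an estimated correlation). TFAP2A rose from 5.06 ± 1.027 to 5689 ± 45.04 (change 9.89 ± 0.14), GATA3 from 3.67 ± 2.46 to 4839 ± 121 (change 10.12 ± 0.26), TFAP2C from 358 ± 7.02 to 3532 ± 36.2 (change 3.30 ± 0.06) and GRHL2 from 452.8 ± 10.5 to 2021 ± 9.58 (change 2.16 ± 0.06). TP63 went from 0 to 89.2 ± 0.52 (at least 59.4-fold higher). Of 28 simple-epithelium genes 23 rose and 3 fell (24 and 3 adjusted over the list alone; adjusted p = 3.63e-07 for the list, and adjusted p = 0.217 with an estimated correlation). KRT7 rose from 119 ± 19.8 to 8348 ± 407, KRT8 from 8645 ± 52.1 to 62168 ± 3956 and KRT18 from 1073 ± 4.91 to 4759 ± 253, while KRT5 and KRT14 had 0 reads in all 4 libraries. All 16 BMP targets tested rose (median 3.64, adjusted p = 2.99e-10, and adjusted p = 0.217 with an estimated correlation). In the amnion list 14 of 17 rose and 3 fell (median 4.18, adjusted p = 1.58e-05, and adjusted p = 0.217 with an estimated correlation). HAND1 measured 2.47 ± 1.96 in hESC and 5094 ± 279 at day 3. Among retinoic acid targets 12 of 14 rose and 1 fell (median 3.08, adjusted p = 1.45e-05, and adjusted p = 0.255 with an estimated correlation), and CYP26A1 rose from 85.3 ± 22.6 to 13574 ± 87.9. Pluripotency genes went both ways, with 7 of 22 higher and 13 lower (14 lower adjusted over the list alone; median -0.94, adjusted p = 0.0350, and adjusted p = 0.647 with an estimated correlation). POU5F1 fell from 40367 ± 243 to 17571 ± 92.1, NANOG from 1748 ± 72.1 to 264 ± 8.57 and SOX2 from 6136 ± 320 to 1200 ± 253. Chromatin modifiers rose in 22 of 32 and fell in 8 (adjusted p = 0.00765, and adjusted p = 0.578 with an estimated correlation), with TET2 from 96.0 ± 2.11 to 521.8 ± 54.2. Mitochondrially encoded mRNAs rose in 10 of 13 and fell in 0 (adjusted p = 0.00574, and adjusted p = 0.578 with an estimated correlation). Counts adjusted over the list alone equalled those over all genes here and later unless both are given.

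The other lists were not called against the remaining genes at day 3, although with the replicate number as a block keratinocyte genes (adjusted p = 0.00286) and WNT targets (adjusted p = 0.00396) were called higher. Keratinocyte genes rose in 10 of 22 and fell in 5, trophoblast genes rose in 2 of 7 and fell in 2, and placode genes rose in 5 of 7 and fell in 1. Neural ectoderm genes rose in 4 of 14 and fell in 7, and neural crest genes rose in 5 of 11 and fell in 6. Of the mesoderm and primitive streak genes 6 of 10 rose and 2 fell, of endoderm genes 4 of 7 rose and 1 fell, and of mesenchymal genes 7 of 17 rose and 8 fell (median 0.08, mean -0.30). WNT targets rose in 8 of 13 and fell in 4, FOXO targets rose in 5 of 18 and fell in 9, the FOXO family rose in 2 of 4 and fell in 2, and the SP family rose in 4 of 8 and fell in 2. Proliferation genes rose in 13 of 26 and fell in 7, and p53 targets rose in 9 of 21 and fell in 10 (11 lower adjusted over the list alone). Interferon response genes fell in 6 of 12 and rose in 0, and ATF4 stress genes rose in 8 of 15 and fell in 4 (median 0.22, mean -0.10). In the trophoblast list the median was -0.07, the mean 0.60 and the test's direction downward. Adjusted p of these lists ran from 0.0842 (placode and WNT targets) to 0.9998 (trophoblast). The FOXO family, with 4 members, was too small for a list test in all 5 comparisons.

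**Figure D2:**
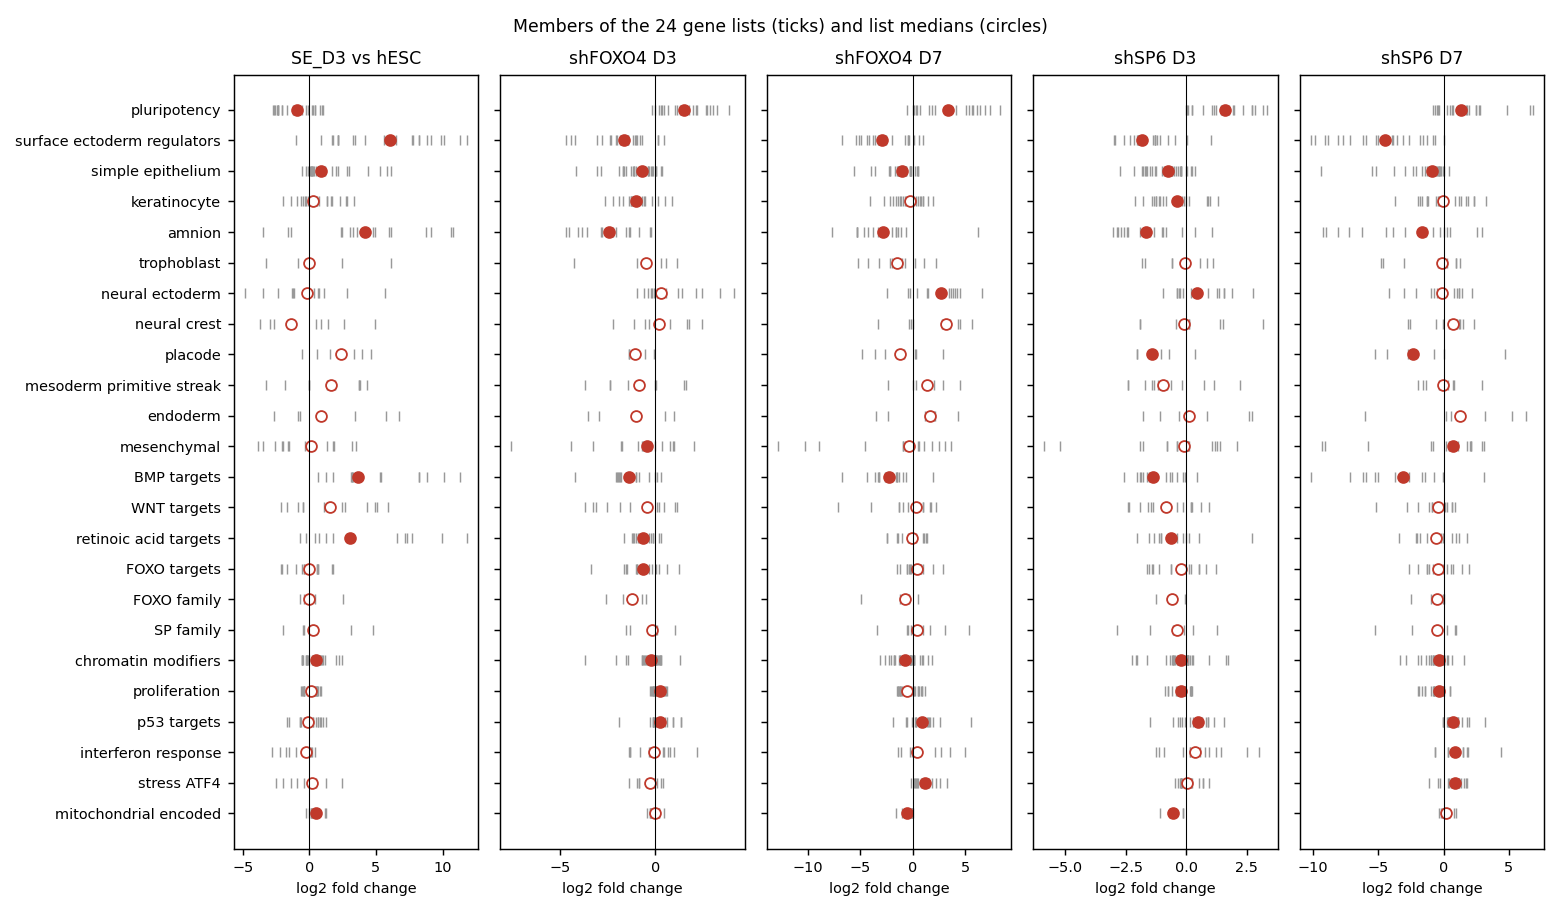
Log2 fold change (horizontal axis) of each member (grey ticks) and the median (circle) of the 24 gene lists in the 5 comparisons, with filled circles for lists at an adjusted p under 0.05 by camera with the preset correlation. The surface ectoderm list has its median at 6.06 in unmodified cells and at -1.63, -2.91, -1.82 and -4.51 in shFOXO4 day 3, shFOXO4 day 7, shSP6 day 3 and shSP6 day 7 cells.

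FOXO4 knockdown cells at day 3 had higher levels of most pluripotency genes and lower levels of most surface epithelium genes than scramble cells. Most simple-epithelium genes, surface ectoderm regulators, amnion genes and BMP targets were among those that lay lower. Under the rule for named genes, with a mean of at least 100, ANKRD1, NPPB, GDF6, FLRT3 and COL3A1 had the largest falls. Of 15697 genes tested, 9838 changed, 4999 higher and 4839 lower, and 969 rose and 1351 fell by at least 2-fold. ANKRD1 fell from 940.5 ± 214.5 to 2.79 ± 0.94, NPPB from 570.3 ± 133 to 4.72 ± 0.66, GDF6 from 1384 ± 86.9 to 16.6 ± 0.94 (change -6.30 ± 0.13) and FLRT3 from 1370 ± 69.1 to 20.1 ± 1.59 (change -6.02 ± 0.12). COL3A1 measured 304 ± 28.4 in scramble and 0.86 ± 1.22 in shFOXO4 cells. By the same rule the 5 highest were OR52A1 (20.2 ± 3.31 to 321 ± 23.9), LEFTY1 (15.5 ± 2.66 to 233.5 ± 19.9), MIR124-1HG (24.8 ± 2.50 to 295.5 ± 18.2), TNFRSF8 (54.4 ± 3.14 to 612 ± 5.82) and POU3F1 (17.6 ± 3.23 to 193.5 ± 7.36).

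Pluripotency genes were higher in 20 of 22 and lower in 1 (median 1.47, adjusted p = 3.96e-14, and adjusted p = 0.127 with an estimated correlation). NANOG rose from 341 ± 13.2 to 1531 ± 72.2 (change 2.16 ± 0.07), SOX2 from 789.6 ± 68.6 to 3382 ± 117 (change 2.10 ± 0.06) and POU5F1 from 15224 ± 541 to 19613 ± 65.9 (change 0.37 ± 0.04). Surface ectoderm regulators were lower in 19 of 22 and higher in 1 (median -1.63, adjusted p = 3.96e-14, and adjusted p = 0.127 with an estimated correlation). TFAP2A fell from 5605 ± 218 to 1137 ± 47.6 (change -2.30 ± 0.05), GATA3 from 4229 ± 94.3 to 1161 ± 19.1 (change -1.86 ± 0.05), TFAP2C from 3626 ± 56.1 to 1749 ± 23.7, GRHL2 from 2318 ± 40.5 to 1022 ± 42.1 and TP63 from 64.3 ± 9.90 to 2.26 ± 1.69. Simple-epithelium genes were lower in 24 of 28 and higher in 2 (median -0.73, adjusted p = 2.41e-11, and adjusted p = 0.127 with an estimated correlation), with KRT8 from 62939 ± 2413 to 19795 ± 681, KRT18 from 6364 ± 644 to 1946 ± 178 and KRT7 from 8790 ± 470 to 484.5 ± 7.43. Keratinocyte genes were lower in 18 of 21 and higher in 2 (adjusted p = 4.01e-06, and adjusted p = 0.127 with an estimated correlation), amnion genes lower in 15 of 17 and higher in 0 (adjusted p = 8.61e-14, and adjusted p = 0.127 with an estimated correlation), and BMP targets lower in 13 of 16 and higher in 1 (adjusted p = 7.38e-09, and adjusted p = 0.127 with an estimated correlation). FOXO targets were lower in 12 of 17 and higher in 3 (adjusted p = 5.00e-04, and adjusted p = 0.181 with an estimated correlation), and SESN3 fell from 5124 ± 103 to 495 ± 12.3. Mesenchymal genes were lower in 10 of 18 and higher in 5 (adjusted p = 0.00570, and adjusted p = 0.240 with an estimated correlation). Retinoic acid targets were lower in 9 of 14 and higher in 2 (adjusted p = 0.00294, and adjusted p = 0.403 with an estimated correlation). Chromatin modifiers were lower in 20 of 32 and higher in 7 (adjusted p = 0.00405, and adjusted p = 0.365 with an estimated correlation), and SMARCA2 fell from 1774 ± 117 to 140 ± 23.4. Proliferation genes were higher in 16 of 26 and lower in 5 (6 lower adjusted over the list alone; adjusted p = 0.00554, and adjusted p = 0.365 with an estimated correlation). For p53 targets 12 of 21 were higher and 3 lower (adjusted p = 0.0375, and adjusted p = 0.571 with an estimated correlation and 0.0631 with the replicate number as a block).

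Lists that were not called against the other genes in shFOXO4 cells at day 3 included those of alternative fates. Neural ectoderm genes were higher in 7 of 16 and lower in 3, neural crest genes higher in 4 of 8 and lower in 4, and placode genes lower in 5 of 6 and higher in 0. Mesoderm and primitive streak genes were lower in 6 of 10 and higher in 2, endoderm genes lower in 3 of 5 and higher in 1, and trophoblast genes lower in 3 of 7 and higher in 2 (median -0.51, mean -0.62, test upward). WNT targets were lower in 6 of 13 and higher in 4, and the SP family lower in 5 of 8 and higher in 0 (1 higher adjusted over the list alone). All 4 members of the FOXO family were lower, and FOXO3 fell from 962 ± 34.2 to 299 ± 27.2. On both days, counts of the FOXO family in shFOXO4 cells and of the SP family in shSP6 cells include the targeted gene. Interferon response genes were lower in 5 of 14 and higher in 4 (median -0.07, mean -0.01, test upward). ATF4 stress genes were lower in 9 of 15 and higher in 2 (3 higher adjusted over the list alone), and mitochondrially encoded mRNAs lower in 5 of 13 and higher in 3. Adjusted p of these lists ran from 0.0600 (placode and ATF4 stress genes) to 0.707 (trophoblast).

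At day 7 the FOXO4 knockdown cells had high levels of pluripotency RNAs and of metallothionein RNAs, the latter almost absent from scramble cells. LUM, DCN and COL3A1, abundant in scramble cells, were at or near 0. Most surface ectoderm regulators, simple-epithelium, amnion and BMP target genes lay below scramble cells, and most neural ectoderm genes were higher. Of 16374 genes tested, 11881 changed, 6081 higher and 5800 lower, and 3519 rose and 2547 fell by at least 2-fold. LUM fell from 1263 ± 47.4 to 0 (at least 842.0-fold lower), DCN from 482 ± 25.3 to 0 (at least 321-fold) and MAGEB3 from 288 ± 81.8 to 0 (at least 192-fold). COL3A1 measured 19655 ± 1498 in scramble and 1.70 ± 0.55 in shFOXO4 cells. Among the highest, MT1G rose from 2.93 ± 0.094 to 3088 ± 151, MT1E from 3.39 ± 1.96 to 1385 ± 116 and LEFTY1 from 3.87 ± 2.64 to 1441 ± 186. MT1H measured 0.96 ± 1.35 in scramble and 1317 ± 43.9 in shFOXO4 cells, and SMIM24 1.91 ± 2.70 and 660.1 ± 6.46. The 4 libraries of this table stood apart from the other tables. Mitochondrially encoded mRNAs took 5.56 to 7.47% of their counts, against 1.31 to 1.78% in the shSP6 day 7 table. The 10 most abundant genes took 9.997 to 12.3%, against 6.50 to 7.08%.

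Pluripotency genes were higher in 18 of 22 and lower in 1 (median 3.34, adjusted p = 2.07e-06, and adjusted p = 0.452 with an estimated correlation). POU5F1 rose from 4399 ± 1259 to 38121 ± 1330 (change 3.15 ± 0.15) and SOX2 from 135 ± 67.5 to 6726 ± 97.1 (change 5.73 ± 0.26). NANOG rose from 47.4 ± 31.6 to 2976 ± 38.1, a change of 6.12 ± 0.36 that was 6.84 without scramble replicate 1 and 5.40 without scramble replicate 2. Surface ectoderm regulators were lower in 18 of 22 and higher in 2 (median -2.91, adjusted p = 2.07e-06, and adjusted p = 0.452 with an estimated correlation). TFAP2A fell from 9184 ± 418 to 661 ± 53.02 (change -3.79 ± 0.07), GATA3 from 8633 ± 1038 to 895 ± 8.12 (change -3.26 ± 0.08), GRHL2 from 2065 ± 115 to 352.5 ± 9.90 and TP63 from 465.5 ± 61.8 to 14.3 ± 3.95. TFAP2C measured 2622 ± 618 and 1513 ± 175, a change of -0.78 ± 0.14 (adjusted p = 8.62e-04) that without shFOXO4 replicate 2 was -0.66 with an adjusted p of 0.0860. Simple-epithelium genes were lower in 24 of 28 and higher in 4 (median -1.0, adjusted p = 4.02e-06, and adjusted p = 0.369 with an estimated correlation), and KRT8 fell from 86632 ± 4199 to 32139 ± 694, KRT18 from 6486 ± 541 to 2489 ± 58.5 and KRT7 from 20739 ± 1221 to 436 ± 11.2. KRT5 was 24.4 ± 0.60 and 31.0 ± 4.88 (change 0.33 ± 0.32, adjusted p = 0.376), and KRT14 was 6.86 ± 1.60 and 14.2 ± 2.28 (change 0.95 ± 0.45, adjusted p = 0.0847). Amnion genes were lower in 15 of 17 and higher in 1 (adjusted p = 2.50e-06, and adjusted p = 0.369 with an estimated correlation), with HAND1 from 9409 ± 822 to 44.6 ± 9.27. BMP targets were lower in 15 of 16 and higher in 1 (adjusted p = 2.07e-06, and adjusted p = 0.452 with an estimated correlation). Neural ectoderm genes were higher in 12 of 16 and lower in 2 (median 2.64, adjusted p = 0.0191, and adjusted p = 0.452 with an estimated correlation), with POU3F1 from 34.01 ± 11.3 to 3227 ± 251. In unmodified cells POU3F1 fell from 916.5 in hESC to 30.9 at day 3, and 7 of 14 members of this list fell there while 4 rose. Expression kept from hESC was not tested for this list in any knockdown.

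Further lists concerned stress and cell state at day 7. For p53 targets 16 of 21 were higher and 3 lower (median 0.91, adjusted p = 3.63e-04, and adjusted p = 0.452 with an estimated correlation), and GDF15 rose from 322.5 ± 22.1 to 15191 ± 1837. ATF4 stress genes were higher in 12 of 15 and lower in 1 (adjusted p = 9.87e-04, and adjusted p = 0.452 with an estimated correlation), with DDIT3 from 16.1 ± 1.56 to 159.6 ± 6.41. Chromatin modifiers were lower in 21 of 32 and higher in 5 (adjusted p = 0.00149, and adjusted p = 0.452 with an estimated correlation). Mitochondrially encoded mRNAs were lower in 9 of 13 and higher in 0 (adjusted p = 0.00536, and adjusted p = 0.584 with an estimated correlation). The remaining lists were not called against the other genes, although with the replicate number as a block keratinocyte genes were called lower (adjusted p = 0.0346) and neural crest genes higher (adjusted p = 0.0263). Keratinocyte genes were lower in 13 of 25 and higher in 5, trophoblast genes lower in 9 of 12 and higher in 2, neural crest genes higher in 6 of 10 and lower in 1, and placode genes lower in 5 of 8 and higher in 1. Mesoderm and primitive streak genes were higher in 4 of 7 and lower in 1, endoderm genes higher in 4 of 6 and lower in 2, and mesenchymal genes lower in 10 of 18 and higher in 7. WNT targets were higher in 7 of 13 and lower in 5 (median 0.26, mean -0.54, test downward), retinoic acid targets lower in 6 of 14 and higher in 4, and FOXO targets higher in 10 of 17 and lower in 5. In the FOXO family 3 of 4 were lower and 1 higher, and in the SP family 4 of 8 were higher and 4 lower. Proliferation genes were lower in 15 of 26 and higher in 8 (9 higher adjusted over the list alone), and interferon response genes higher in 5 of 13 and lower in 3. Adjusted p of these lists ran from 0.0640 (trophoblast) to 0.912 (WNT targets and SP family).

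SP6 knockdown cells at day 3 resembled the FOXO4 knockdown in direction, with most pluripotency genes higher and most surface epithelium genes lower than in scramble cells. COL3A1 and ANKRD1 were again among the genes with the largest falls under the rule for named genes. Of 16548 genes tested, 9232 changed, 4676 higher and 4556 lower, and 1395 rose and 1281 fell by at least 2-fold. The count ranged from 6997 to 10472 when each library was left out in turn. COL3A1 fell from 334 ± 121 to 10.3 ± 9.98, a change of -5.20 ± 0.53 that was -4.14 and -6.26 without shSP6 replicates 1 and 2. CA3 fell from 441 ± 2.63 to 25.7 ± 6.60, ANKRD1 from 1674 ± 2.02 to 120.6 ± 24.2, ADAMTS9 from 628 ± 222 to 46.0 ± 19.3 and UNC5C from 1128 ± 422 to 82.2 ± 20.2. The highest were TNFAIP6 (6.41 ± 1.92 to 202 ± 33.8), MYH2 (19.4 ± 3.97 to 478 ± 51.7), SORBS2 (15.8 ± 3.46 to 243 ± 15.5), DLL3 (52.98 ± 13.7 to 657 ± 54.8) and PPP1R17 (100.1 ± 61.5 to 1067 ± 37.7). PPP1R17 changed by 3.55 ± 0.31, and by 2.88 and 4.21 without scramble replicates 1 and 2.

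Pluripotency genes were higher in 19 of 22 and lower in 0 (median 1.62, adjusted p = 1.77e-10, and adjusted p = 0.318 with an estimated correlation). NANOG rose from 674 ± 57.0 to 2696 ± 151 (change 2.0 ± 0.08), SOX2 from 1371 ± 414 to 4583 ± 135 (change 1.77 ± 0.15) and POU5F1 from 14347 ± 1849 to 23021 ± 362 (change 0.69 ± 0.08). Surface ectoderm regulators were lower in 20 of 22 and higher in 1 (median -1.82, adjusted p = 1.77e-10, and adjusted p = 0.318 with an estimated correlation). TFAP2A fell from 6223 ± 1339 to 1385 ± 185 (change -2.16 ± 0.13), GATA3 from 5039 ± 769 to 1233 ± 151 (change -2.03 ± 0.10), TFAP2C from 3691 ± 260.0 to 1536 ± 52.2, GRHL2 from 2535 ± 62.5 to 1028 ± 59.6 and TP63 from 199 ± 47.4 to 25.01 ± 9.08. Simple-epithelium genes were lower in 22 of 28 and higher in 2 (median -0.73, adjusted p = 4.81e-08, and adjusted p = 0.318 with an estimated correlation), with KRT8 from 93496 ± 5042 to 26696 ± 2945, KRT18 from 8096 ± 412 to 2649 ± 282 and KRT7 from 14206 ± 1773 to 2161 ± 429. Keratinocyte genes were lower in 13 of 22 and higher in 4 (adjusted p = 0.0120, and adjusted p = 0.318 with an estimated correlation), amnion genes lower in 14 of 17 and higher in 1 (adjusted p = 3.32e-07, and adjusted p = 0.318 with an estimated correlation), placode genes lower in 6 of 7 and higher in 1 (adjusted p = 0.0146, and adjusted p = 0.318 with an estimated correlation), and neural ectoderm genes higher in 8 of 16 and lower in 1 (adjusted p = 0.0312, and adjusted p = 0.318 with an estimated correlation). BMP targets were lower in 13 of 16 and higher in 1 (14 lower adjusted over the list alone; adjusted p = 3.32e-07, and adjusted p = 0.318 with an estimated correlation), retinoic acid targets lower in 8 of 14 and higher in 2 (adjusted p = 0.0176, and adjusted p = 0.318 with an estimated correlation), and p53 targets higher in 14 of 21 and lower in 4 (adjusted p = 0.0124, and adjusted p = 0.318 with an estimated correlation). Mitochondrially encoded mRNAs were lower in 10 of 13 and higher in 0 (12 lower adjusted over the list alone; adjusted p = 4.86e-04, and adjusted p = 0.419 with an estimated correlation). They took 2.36 and 1.83% of counts in the scramble libraries and 1.52 and 1.60% in the shSP6 libraries. Across day 3 groups this share differed by more, from 1.07% in a scramble library of shFOXO4 to 3.38% in an unmodified library. The rise called in unmodified day 3 cells has the same limit. Chromatin modifiers were lower in 16 of 33 and higher in 6 (adjusted p = 0.0289, and adjusted p = 0.419 with an estimated correlation), and proliferation genes lower in 12 of 26 and higher in 5 (14 lower adjusted over the list alone; adjusted p = 0.0263, and adjusted p = 0.419 with an estimated correlation).

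In the remaining lists of shSP6 day 3 cells, trophoblast genes were lower in 4 of 9 and higher in 3 (median -0.05, mean -0.24, test upward), neural crest genes higher in 3 of 11 and lower in 2 (median -0.07, mean 0.16), and mesoderm and primitive streak genes lower in 8 of 12 and higher in 2. Endoderm genes were higher in 3 of 7 and lower in 2, mesenchymal genes lower in 7 of 18 and higher in 5, and WNT targets lower in 8 of 15 and higher in 4. FOXO targets were lower in 8 of 18 and higher in 5, the FOXO family lower in 3 of 4, and the SP family lower in 5 of 9 and higher in 2. Interferon response genes were higher in 8 of 15 and lower in 2 (3 lower adjusted over the list alone), and ATF4 stress genes higher in 5 of 15 and lower in 5 (6 lower adjusted over the list alone). IFIT3 rose from 18.4 ± 4.04 to 153 ± 8.39. Adjusted p of these lists ran from 0.0602 (interferon response) to 0.983 (trophoblast).

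At day 7 the SP6 knockdown cells had lost most RNA of several surface ectoderm regulators, among them DLX5, TFAP2A and TFAP2B. LEFTY1, LEFTY2 and CER1 were among the genes with the largest rises under the rule for named genes. Most interferon response genes, p53 targets and ATF4 stress genes were higher than in scramble cells. Most proliferation genes were lower. Of 17535 genes tested, 10268 changed, 5084 higher and 5184 lower, and 2357 rose and 1924 fell by at least 2-fold. TFAP2B fell from 911 ± 213 to 0 (at least 607-fold lower). DLX5 measured 1487 ± 409.8 in scramble and 0.32 ± 0.45 in shSP6 cells, KRT23 1308 ± 351.5 and 0.93 ± 0.42, COL3A1 4197 ± 2568 and 4.95 ± 1.66, and HAND1 2645 ± 1277 and 4.08 ± 4.04. LEFTY2 rose from 333 ± 52.1 to 33442 ± 347 (change 6.66 ± 0.10), LEFTY1 from 39.2 ± 13.5 to 4567 ± 170.3 (change 6.87 ± 0.19), CER1 from 4.51 ± 1.68 to 437 ± 34.02, SFTA1P from 7.81 ± 4.61 to 433 ± 38.8 and IL1A from 16.7 ± 10.8 to 820.5 ± 37.9. IL1A changed by 5.68 ± 0.35, and by 5.02 and 6.34 without scramble replicates 1 and 2.

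Surface ectoderm regulators were lower in 21 of 22 and higher in 0 (median -4.51, adjusted p = 1.60e-13, and adjusted p = 0.414 with an estimated correlation). TFAP2A fell from 4448 ± 836 to 7.16 ± 1.46 (change -9.09 ± 0.19), GATA3 from 4330 ± 717 to 129 ± 13.2 (change -5.05 ± 0.13), GRHL2 from 2368 ± 294 to 269 ± 14.7 (change -3.13 ± 0.11) and TFAP2C from 1970 ± 383 to 668 ± 47.1 (change -1.55 ± 0.13). TP63 measured 472 ± 38.8 in scramble and 1.24 ± 0.026 in shSP6 cells. Simple-epithelium genes were lower in 24 of 28 and higher in 1 (adjusted p = 5.66e-09, and adjusted p = 0.414 with an estimated correlation), with KRT8 from 101433 ± 7216 to 23993 ± 70.6, KRT18 from 8384 ± 1582 to 2715 ± 371 and KRT7 from 13707 ± 3313 to 309 ± 13.8. Pluripotency genes were higher in 17 of 22 and lower in 5 (median 1.34, adjusted p = 2.62e-04, and adjusted p = 0.506 with an estimated correlation). POU5F1 rose from 22622 ± 4338 to 55285 ± 65.5 (change 1.303 ± 0.11), NANOG from 561 ± 227 to 2938 ± 14.7 (change 2.45 ± 0.21) and SOX2 from 1691 ± 630 to 3814 ± 12.03 (change 1.22 ± 0.19). BMP targets were lower in 14 of 16 and higher in 1 (median -3.12, adjusted p = 2.35e-08, and adjusted p = 0.414 with an estimated correlation). Amnion genes were lower in 11 of 17 and higher in 2 (adjusted p = 0.00102, and adjusted p = 0.416 with an estimated correlation). Placode genes were lower in 4 of 7 and higher in 1 (5 lower adjusted over the list alone; adjusted p = 0.0460, and adjusted p = 0.414 with an estimated correlation). Mesenchymal genes were higher in 12 of 18 and lower in 5, with a median of 0.72, a mean of -0.42 and an upward test (adjusted p = 0.0460, and adjusted p = 0.414 with an estimated correlation), and VIM rose from 344 ± 21.7 to 2905 ± 87.8.

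For p53 targets 18 of 21 were higher and 0 lower in shSP6 cells at day 7 (adjusted p = 1.90e-06, and adjusted p = 0.414 with an estimated correlation), with CDKN1A from 2030 ± 494 to 7861 ± 566. Interferon response genes were higher in 10 of 14 and lower in 1 (median 0.84, adjusted p = 0.00387, and adjusted p = 0.414 with an estimated correlation), with ISG15 from 85.3 ± 3.06 to 293.5 ± 4.07. ATF4 stress genes were higher in 11 of 15 and lower in 3 (12 higher adjusted over the list alone; adjusted p = 0.00633, and adjusted p = 0.474 with an estimated correlation). Chromatin modifiers were lower in 20 of 33 and higher in 4 (21 lower adjusted over the list alone; adjusted p = 5.18e-04, and adjusted p = 0.414 with an estimated correlation). Proliferation genes were lower in 18 of 26 and higher in 2 (19 lower adjusted over the list alone; adjusted p = 2.57e-04, and adjusted p = 0.414 with an estimated correlation), with MCM3 from 9916 ± 609 to 2703 ± 215. Lists that were not called against the other genes were keratinocyte genes (8 of 25 higher and 10 lower, median -0.04, mean 0.04), trophoblast genes (3 of 10 higher and 4 lower), and neural ectoderm genes (6 of 14 higher and 5 lower, 6 lower adjusted over the list alone, median -0.16, mean -0.29, test upward). The same held for neural crest genes (5 of 10 higher and 2 lower, 6 higher adjusted over the list alone), mesoderm and primitive streak genes (2 of 9 higher and 3 lower) and endoderm genes (4 of 7 higher and 1 lower). WNT targets were higher in 1 of 13 and lower in 7 (4 higher adjusted over the list alone), retinoic acid targets higher in 4 of 14 and lower in 8 (called lower with the replicate number as a block, adjusted p = 0.0455), and FOXO targets higher in 4 of 17 and lower in 10 (5 higher adjusted over the list alone). The FOXO family was lower in 2 of 4, and the SP family higher in 1 of 8 and lower in 5 (3 higher adjusted over the list alone). Mitochondrially encoded mRNAs were higher in 4 of 13 and lower in 1. Adjusted p of these lists ran from 0.0706 (endoderm) to 0.876 (neural ectoderm).

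Most genes that unmodified cells raise by day 3 lay lower in all 4 knockdown comparisons, and genes that they lower tended to lie higher. Both sets were the 500 genes with the largest change in unmodified cells, which share no library with the knockdown comparisons. Of the raised genes, 388 of 462 tested were lower in shFOXO4 cells at day 3 (84.0%, against 29.2% of the other genes), with a median change of -1.72. The number was 365 of 450 in shFOXO4 cells at day 7 (81.1% against 34.1%, median -2.40). In shSP6 cells it was 409 of 490 at day 3 (83.5% against 25.8%, median -1.50) and 387 of 465 at day 7 (83.2% against 28.1%, median -2.72). Camera p-values of the raised set were 7.98e-42, 2.13e-22, 1.32e-35 and 2.22e-34 in that order. With an estimated correlation these p-values were 0.00680, 0.0216, 0.113 and 0.108, so the shSP6 calls did not hold. Of the lowered genes, 197 of 275 were higher in shFOXO4 cells at day 3 (71.6% against 31.1% of the other genes, median 1.10). At day 7 they were 408 of 427 (95.6% against 35.6%, median 3.80, or 3.78 with genes at 0 set at their bound). In shSP6 cells 273 of 353 were higher at day 3 (77.3% against 27.2%, median 1.38) and 365 of 454 at day 7 (80.4% against 27.6%, median 1.52). Camera p-values of the lowered set were 3.49e-14, 1.31e-29, 4.29e-24 and 4.62e-23, and with an estimated correlation 0.0114, 0.0243, 0.0988 and 0.271, where again the shSP6 calls did not hold. The filter on low levels took out 217 of 492 lowered genes in the shFOXO4 day 3 table, and a gene near 0 in scramble cells passes it mainly when the knockdown raises it. An alternative with no filter beyond a mean above 0 was therefore added after seeing the data. It gave 237 of 492 and 443 of 500 lowered genes higher in shFOXO4 cells at day 3 and day 7, and 296 of 493 and 335 of 499 in shSP6 cells, with medians of 0.96, 3.56, 1.23 and 1.497.

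**Figure D3:**
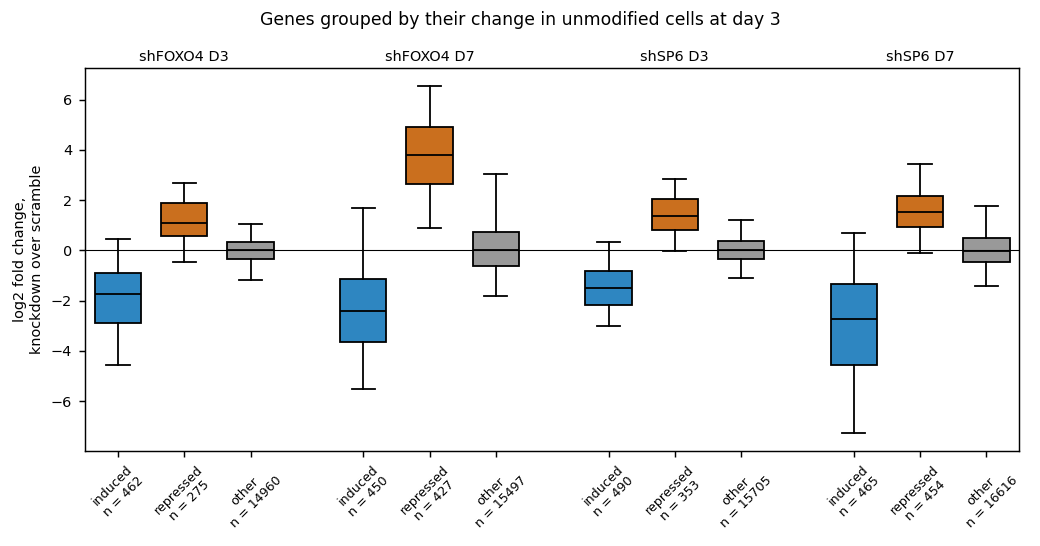
Log2 fold change of knockdown over scramble (vertical axis) for the 500 genes most raised (blue), the 500 most lowered (orange) and all other genes (grey) in unmodified day 3 cells, as far as tested, with boxes from the lower to the upper quartile, a line at the median and whiskers from the 5th to the 95th percentile. Medians of the raised set lie between -2.72 and -1.50 and those of the lowered set between 1.10 and 3.80.

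Both knockdowns moved many of the same genes in the same direction on each day. At day 3 the fold changes of shFOXO4 and shSP6 cells correlated across 15476 genes with Pearson r = 0.735 and Spearman rho = 0.639, and at day 7 across 16043 genes with r = 0.742 and rho = 0.700. Genes are not independent replicates, so no p-value is given. At day 3, 2863 genes were higher and 2980 lower in both, against 1398 and 1374 by chance from the numbers called, while 312 and 371 were called in opposite directions against 1414 and 1359 by chance. Day 7 had 3444 genes higher and 3596 lower in both, against 1743 and 1795 by chance, and 501 and 381 in opposite directions against 1889 and 1656. NANOG, SOX2, POU5F1 and LEFTY1 were among the genes higher in both knockdowns on both days, and TFAP2A, GATA3, KRT8 and SP6 among those lower.

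**Figure D4:**
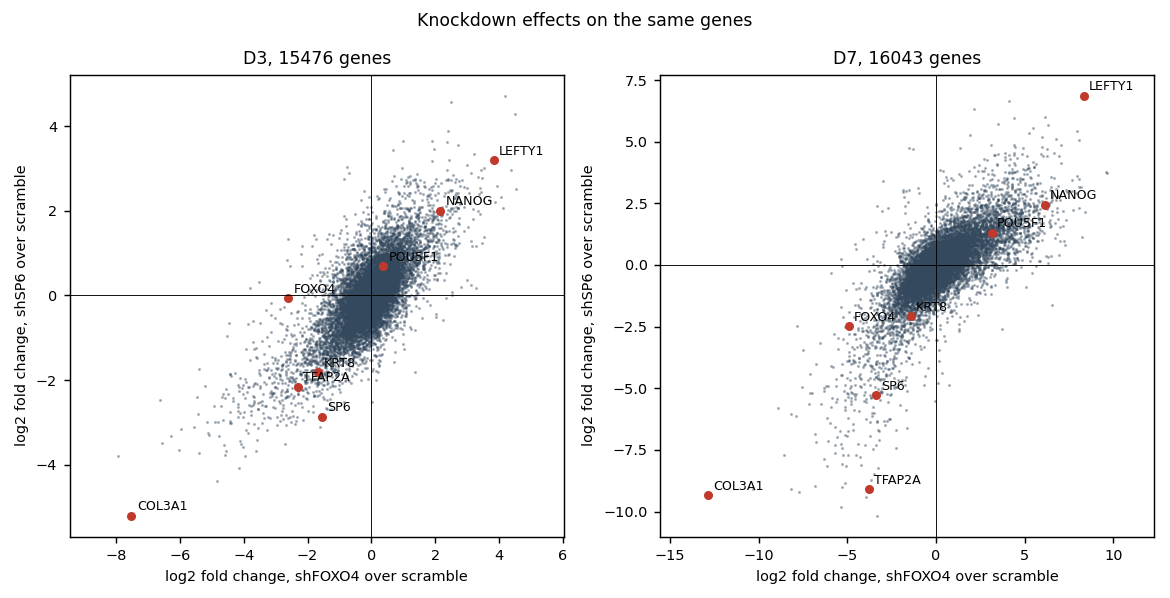
Log2 fold change over scramble of each gene (points) in shFOXO4 cells (horizontal axis) and shSP6 cells (vertical axis) at day 3 (left, 15476 genes) and day 7 (right, 16043 genes), with 8 named genes in red. FOXO4 lies at -2.60 and -0.06 at day 3 and at -4.92 and -2.49 at day 7, and the position of COL3A1 depends on the pseudocount because few or no reads were left.

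Knockdown effects differed between the days and between the 2 knockdowns at many genes. The FOXO4 knockdown changed more between the days than the SP6 knockdown by count. In the SP6 knockdown the falls of DLX5, TFAP2A and TFAP2B deepened from day 3 to day 7. In shFOXO4 cells the effect differed between day 7 and day 3 for 9383 of 14954 genes (62.8%), and in shSP6 cells for 5608 of 15992 (35.1%). Between shSP6 and shFOXO4 cells the effect differed for 5698 of 15476 genes (36.8%) at day 3 and for 7868 of 16043 (49.0%) at day 7. STC1 changed by -1.10 in shFOXO4 cells at day 3 and by 5.36 at day 7, a difference of 6.46 ± 0.17 (adjusted p = 7.61e-12). TFAP2A changed by -2.16 and -9.09 in shSP6 cells at day 3 and day 7, a difference of -6.93 ± 0.24 (adjusted p = 6.83e-09). ACTA1 at day 7 changed by -1.31 in shFOXO4 and by 4.72 in shSP6 cells, a difference of 6.03 ± 0.18 (adjusted p = 1.52e-09). For FOXO4 the effects of the 2 hairpins differed by 2.54 ± 0.11 at day 3 (adjusted p = 1.68e-10) and by 2.43 ± 0.19 at day 7 (adjusted p = 1.88e-06). For SP6 they differed by -1.31 ± 0.20 at day 3 (adjusted p = 9.53e-05) and by -1.92 ± 0.17 at day 7 (adjusted p = 4.49e-06). Each effect is against its own scramble group, and these groups differed. At day 7 POU5F1 measured 4399 in the scramble cells of shFOXO4 and 22622 in those of shSP6, and COL3A1 19655 and 4197. Mitochondrially encoded mRNAs took 7.17 and 7.47% of counts in the former and 1.31 and 1.55% in the latter. The tests therefore do not separate the hairpin from its control culture.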

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

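In this part the tests of a mixture of cells, of the SP6 hairpin acting on FOXO4 RNA and of the interferon response were chosen only after the result was seen, while the 2 comparisons of FOXO4 with matched genes were chosen before.

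Knockdown effects differed between days and between knockdowns at many genes, each against its own scramble group, and these groups differed as well. Every item in this and the next paragraph stands here because a test of the difference between 2 knockdown effects passed its threshold. From day 3 to day 7 the FOXO4 knockdown effect differed for 9383 genes and the SP6 knockdown effect for 5608. Between the SP6 and the FOXO4 knockdown, 5698 genes differed at day 3 and 7868 at day 7. In the FOXO4 knockdown the effect at day 7 minus that at day 3 was most negative for COL3A1 (-5.31), TMEM132E (-4.99) and PTN (-4.33) and most positive for TLE2 (7.14), CALCR (6.67) and STC1 (6.46), all in log2 units, among named genes. For FOXO4 itself it was -2.32 and for SP6 -1.82. In the SP6 knockdown it was most negative for DLX5 (-8.26), TFAP2A (-6.93) and TFAP2B (-6.87) and most positive for NPPB (5.53), CXCL1 (4.29) and ARHGAP40 (3.87), with FOXO4 at -2.43 and SP6 at -2.42. In shFOXO4 cells COL3A1 kept few or no reads on both days. Its difference of -5.31 therefore follows the higher scramble level at day 7 and does not show a knockdown effect that grew.

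The SP6 knockdown effect minus the FOXO4 knockdown effect at day 3 was most negative for H2AC6 (-3.11), MIR124-1HG (-2.15) and NEFH (-2.08) and most positive for ANKRD1 (4.16), NPPB (4.15) and SEMA3C (3.83). FOXO4 differed by 2.54 and SP6 by -1.31, each gene falling more in the knockdown aimed at it. At day 7 the difference was most negative for SMIM24 (-7.12), DLX5 (-6.84) and BARX1 (-6.45) and most positive for ACTA1 (6.03), ACTC1 (5.59) and COL6A3 (5.40), with FOXO4 at 2.43 and SP6 at -1.92. ACTA1 rose in shSP6 cells (4.72) and fell in shFOXO4 cells (-1.31). With 1 library left out 5 of these differences moved by over 1.5-fold: COL3A1 ran from -6.04 to -4.59, TLE2 from 6.52 to 7.76, SMIM24 from -8.25 to -5.98, BARX1 from -7.53 to -5.37 and COL6A3 from 4.54 to 6.27. The order among named genes is therefore not settled. A pseudocount of 5 moved TMEM132E (to -4.28), CALCR (5.97), DLX5 (-6.22 over the days and -4.82 between the knockdowns), TFAP2B (-4.65), ANKRD1 (3.16), NPPB at day 3 (3.42) and SMIM24 (-5.55) by over 1.5-fold. It moved TFAP2A (to -6.36) and COL3A1 (to -5.79) by less.

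Genes that unmodified cells raise over 50-fold by day 3, with a scramble mean of at least 100, were mostly lower in both knockdowns at day 3. In shFOXO4 cells the median was -2.40 (86 genes, 6 not called lower, 4 of these higher). In shSP6 cells it was -2.14 (111 genes, 5 not called lower, 2 of these higher). A culture in which some cells stayed undifferentiated and the rest differentiated normally would lower all of them by 1 common ratio. Their log2 fold changes spanned 4.01 from the 10th to the 90th percentile in shFOXO4 cells and 2.35 in shSP6 cells, 15.1 and 6.38 times the spans that standard errors between replicates give. Between the control groups of day 3, which were scaled separately, the same genes spanned 1.201 to 1.81 and 1.55 to 1.90, so cultures differ by more than replicates do. At 2.22 and 1.23 times the largest control span, short of 3 times, a simple mixture cannot be told apart from cells that differentiated in part or from effects on single genes. The few genes called higher go against 1 common ratio for all, but cultures also differ by themselves, so these genes do not decide it.

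FOXO4 RNA was lower in shSP6 cells at day 7 and not called lower at day 3. A hairpin against SP6 that also cut FOXO4 RNA would lower it on both days, and the day 3 change of -0.061 (-0.21 without scramble replicate 1 and 0.086 without scramble replicate 2) argues against this as the main cause of the day 7 change. Matched genes, raised by differentiation about as much as FOXO4 and with a scramble mean of at least 100, were mostly lower too. That limit leaves out genes low in scramble cells, which favours falls. At day 7, 195 of 232 were lower with a median of -1.62, and FOXO4 lay at percentile 30.2 of them. At day 3, 198 of 240 were lower with a median of -1.11, and FOXO4 lay at percentile 87.5. The 5th to 95th percentile of matched genes was wide (-4.36 to 0.83 at day 7 and -2.39 to 0.57 at day 3), so most genes would lie within it. At day 3 FOXO4 was not called lower while most matched genes were. The comparison therefore cannot tell whether FOXO4 at day 7 shared a fall with other differentiation genes. A direct action of SP6 on FOXO4 stays open and was not tested.

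Interferon response genes were higher in 10 of 14 in shSP6 cells at day 7, while in shFOXO4 cells 5 of 13 were higher and the list was not called (adjusted p = 0.229). In shFOXO4 cells the members not called lower in unmodified day 3 cells, or not tested there, had a median change of 0.10. Of these, 1 of 7 was higher, which argues against an interferon response across the list. Members that differentiation lowers exceeded those others by 2.29, and 4 of 6 were higher. Only 3 of 6 lay within 2-fold of their hESC mean, 2 lay above and 1 below, so expression kept at the hESC level stays open. In shSP6 cells the median of members not called lower in unmodified day 3 cells, or not tested there, was 0.77. Of these, 5 of 8 were higher, which may reflect an interferon response. Kept expression there cannot be told apart from it, because the members that differentiation lowers exceeded the others by only 0.37.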

How the results depend on the processing

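For the raised and lowered sets, the alternative with no filter was chosen only after the result was seen, and all 8 of its camera calls stayed. Across the alternatives other than leaving out a library, 142 main values and counts kept their call or moved by less than the limit set for them (1.5 times for a count), 14 moved and 4 lost their call, and none reversed; all 116 values with 1 library left out stayed within 1.5 times the main value or on the same side of the threshold. Counts of changed genes ranged over the left-out libraries from 10239 to 10499 (unmodified SE day 3), 8875 to 9288 (shFOXO4 day 3), 9763 to 11030 (shFOXO4 day 7), 6997 to 10472 (shSP6 day 3) and 7961 to 10012 (shSP6 day 7). A fold limit of 2 left 4642, 2320, 6066, 2676 and 4281 genes in that order, by its construction. With an estimated correlation camera called 0 lists in each of the 5 comparisons, where the preset correlation called 8, 12, 10, 13 and 12, and the raised set in shSP6 cells had p = 0.113 (day 3) and 0.108 (day 7) and the lowered set 0.0988 and 0.271; the cause was not tested, and groups of 2 give that estimate few degrees of freedom. Fry, which does not compare a list with other genes, called 21 lists in unmodified cells, 18 in shFOXO4 day 7 and 19 in shSP6 day 7 cells. The correlation of the 2 knockdowns at day 3 was 0.775 for genes with a mean of at least 100, which leaves out the low genes. With the replicate number as a block (replicate block), 11951, 10030, 12102, 8879 and 10073 genes changed, 10, 11, 12, 13 and 13 lists were called and 9394, 5086, 5550 and 7544 differences; the samples share only a number, and the gap between replicates 1 and 2 of a control group correlated with that of its case group at -0.012, 0.059, 0.017, -0.050 and -0.020 across genes. edgeR called 11891, 9935 and 10414 genes and DESeq2 10097, 7639 and 8510 in unmodified SE day 3, shFOXO4 day 3 and shSP6 day 7 cells; both were not run for the other 2 tables, nor edgeR for differences, because reads were not recovered in 1 library of each. Of the named genes, 4836 values kept their call or lack of one and 26 lost it (11 with DESeq2, and 5 each with quantile normalization, no filter and 1 fit over all 20 libraries), and with 1 library left out 2124 did (78 of them with a fold change moved by over 1.5-fold), 35 lost a call and 1 gained one, FOXO4 in shSP6 day 3 cells. The named differences kept their call in all 128 values, and in all 256 with 1 library left out, although sizes moved. Gene lists gave 242 unchanged calls, 45 newly called and 58 no longer called. Depth limits genes at 0 or a few reads, whose fold changes follow the pseudocount.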

Other observations

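Tests of gene families in this part were chosen only after the result was seen. Metallothioneins were picked because their members stood among the genes with the largest changes, while changes of the mitochondrial ribosomal RNAs were smaller.

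Metallothionein genes, which bind metal ions, nearly vanished on the way from hESC to SE day 3 and were mostly higher in knockdown than in scramble cells. All 6 members tested fell in unmodified day 3 cells (median -8.44, or -8.14 with genes at 0 set at their bound), and MT2A went from 1532 to 10.6. They were higher in shFOXO4 cells at day 3 (5 of 5, median 2.30) and at day 7 (7 of 7, median 6.77, or 6.60 at the bound), and in shSP6 cells at day 3 (4 of 5, median 2.20) and at day 7 (6 of 6, median 2.98). These counts favour rises, because a member near 0 in scramble cells passes the filter on low levels mainly when the knockdown raises it. MT1F, for example, measured 3.11 in scramble and 21.6 in shFOXO4 cells at day 3. At day 3 MT1G reached only 92.3 in shFOXO4 and 70.4 in shSP6 cells, far below the 3062 of hESC in a separately scaled table, and the day 7 scramble cells of shSP6 already held 363 ± 290. TMM factors and quantile normalization gave the same counts. Reads shared between these similar genes were not examined.

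The mitochondrial ribosomal RNA MT-RNR2 fell from 161095 to 66658 in unmodified day 3 cells. It was higher in all 4 knockdowns than in scramble cells: 113155 against 62240 in shFOXO4 day 3, 528901 against 245878 in shFOXO4 day 7, 102365 against 85429 in shSP6 day 3 and 210588 against 103459 in shSP6 day 7 cells, under TMM factors and quantile normalization as well. MT-RNR1 was lower in shSP6 day 3 cells (7033 against 8978). Libraries were prepared with an mRNA kit, per the labels' protocols.

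Each library was also ranked against the unmodified groups over 16166 genes, across separately scaled tables and without a test. Spearman rho of shFOXO4 day 7 libraries was 0.939 and 0.937 with the hESC mean and 0.886 and 0.883 with the SE day 3 mean, and that of shSP6 day 7 libraries 0.931 and 0.937 with hESC and 0.864 and 0.876 with SE day 3. Scramble libraries of day 7 lay nearer to SE day 3 (0.940 to 0.951) than to hESC (0.848 to 0.909). At day 3 knockdown libraries had rho of 0.925 to 0.928 with hESC and 0.947 to 0.952 with SE day 3.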
